A study of Mus musculus with 9 samples.

How the data were processed

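The series holds 9 single-cell libraries of mouse cells. KP is a lung cancer line with an activated Kras allele and no p53, and its mitochondria carried a red fluorescent protein. KP cells were cultured alone or with CD8+ T cells from spleen whose mitochondria were stained green, and T cells were also cultured alone. The labels give 2 experiments, called benchmarks 1 and 2. Single-cell RNA sequencing (scRNA-seq) covers the 3 groups in both benchmarks, with 10x 5' gene expression libraries, and mtscATAC-seq, which reads open chromatin together with mitochondrial DNA, covers the 3 groups in benchmark 2. The title of the ATAC library of KP cells cultured alone names an RNA assay, but its description and molecule give ATAC and its cells stand in the ATAC tables, so it was used as ATAC. Nothing in the labels says that the benchmarks were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

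Per the submitters' processing notes, reads were mapped to mm10 and assigned to cells with Cell Ranger 6.0.0 and Cell Ranger ATAC 2.0.0, and Seurat was used. The deposited expression tables hold the natural log of 1 plus the UMIs of a gene scaled to 10000 per cell. The scaled values summed to 10000 in every cell, and 100% of them were whole UMIs within 0.05 once divided by the cell's own step. The deposited coverage tables hold read counts at each of the 16299 mitochondrial positions in each cell, and the deposited variant tables hold counts of variant and total reads per cell and site. Each total equalled the coverage at the same position and cell. A table of cells names the sample of each cell and gives its count of mitochondrial reads. The lowest count was 1002 in both RNA tables and 2001 in the ATAC table, so cells with fewer mitochondrial reads are not analysed here. The variant caller, the base quality filter and the removal of duplicate reads are not given in the sources used here. Positions in the deposited tables count from 0, and those printed count from 1 on the mitochondrial genome of GRCm38, the assembly of mm10. Genes were taken from a RefSeq gene table of GRCm38.p6, and reference bases from the variant tables. No genome sequence was used. Doublets were not called, and no cell was removed from the main results.

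Cells are not replicates, so each library was summarised. Log values were turned back to values per 10000 and averaged over the cells of a library. Genes with a mean of at least 0.05 in 2 libraries were kept, which left 10554, and log2(mean + 0.05) was fitted with limma 3.58.1 (R 4.3.3) on all 6 RNA libraries, with terms for group and benchmark and empirical Bayes moderation. Log2 differences are on this scale, which understates those of low genes. P-values were adjusted by Benjamini and Hochberg, and genes under 0.05 were called. The fit had 2 residual degrees of freedom and a prior of 6.29. The benchmark was kept as a term because the labels number the experiments and each benchmark has its own table. The libraries' deviations from their group means within a benchmark correlated at 0.146 for the cocultured and monocultured KP libraries, 0.160 for the cocultured KP and T cell libraries and 0.202 for the monocultured KP and T cell libraries. The 22 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, and the erythroid list had no testable member. Named genes are the 10 highest and 10 lowest by the smaller of both benchmarks' differences, among genes with the same sign in both and at least 0.2 per 10000 in a KP group of each, and examples from the up to 4 members of each list with the largest difference. Named sites are the 10 with the largest difference per table and those that met the rule in 2 tables. A KP variant in the ATAC table and the DNA level of RNA sites were also followed.

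A mitochondrial allele was called T-enriched when coverage was at least 100 reads in the T cells and in 1 of 2 random parts of the monocultured KP cells, its share was at least 1% in T cells and at least 5 times that in the KP part, and the exact 95% intervals did not overlap. KP-enriched alleles met the mirrored rule. Shares in KP cells cultured alone were then measured in the other part, since choosing sites for a low share there would make it rise elsewhere by chance. Shares of cells with an allele were taken after thinning each cell to a fixed number of reads over the sites, the 25th percentile of the KP cells, leaving out shallower cells. A mixing share was fitted by least squares, with 2000 resamples of the sites. Each table has 1 library per group, and no test was made. Exact (Clopper-Pearson) 95% intervals and the limit of 3 reads for a share of 0 cover counting error only, and reads are not independent molecules.

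Both procedures were tested on simulated data. In the libraries' counts with 200 of 10419 genes changed in the cocultured group, limma found 48% of 4-fold and 97% of 16-fold changes at a spread between libraries of 0.2 (SD, log2) and 0% of either at 0.4. edgeR found 100% of both at 0.2, and 97% and 100% at 0.4. The site rule found 100% of 200 planted alleles in each table, and a planted mixing share of 5% was estimated at 4.99%, 5.03% and 4.98%. Unchanged groups were simulated around the monocultured KP libraries with the spread of each gene in the limma fit. Alternatives set before the data were examined changed the pseudocount, filters, scaling, block, libraries, site rule, cell sets and read minimum. Alternatives chosen after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered UMIs summed per library, KP cells with at least 5000 UMIs, cells under 10% mitochondrial UMIs, sites chosen in ATAC and measured in RNA, and the gene list tests with no block or an estimated correlation. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Biopython 1.88 and matplotlib 3.10.9.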

Results

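The study asked whether single-cell reads can show a transfer of mitochondria from CD8+ T cells to KP lung cancer cells in coculture. In scRNA-seq benchmark 1 there were 2904 cocultured KP cells, 7572 monocultured KP cells and 1669 T cells, with 124234616, 220246316 and 8539386 UMIs in total. Benchmark 2 held 1151, 2543 and 1557 cells in the same order, with 30007588, 138928307 and 29345592 UMIs. The mtscATAC-seq tables of benchmark 2 held 3219, 4928 and 8050 cells. Median UMIs per cell were 36287.5, 30100.5 and 5229 in benchmark 1 and 24983, 54042 and 17325 in benchmark 2. Median mitochondrial reads per cell in ATAC were 9357 in cocultured KP cells, 2522 in monocultured KP cells and 8675.5 in T cells.

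The first question was whether T cell mitochondrial DNA could be read in KP cells after coculture. In mtscATAC-seq a single allele marked the T cells. This was G2443A in mt-Rnr2, the gene of the large mitochondrial ribosomal RNA (chromosome MT, 1094 to 2675), within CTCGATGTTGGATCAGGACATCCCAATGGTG (2428 to 2458). It made up 23.3% of T cell reads at the site (135026 of 579135). In KP cells cultured alone it was 1 of 334783 reads, and in cocultured KP cells 0.935% (2479 of 265269, exact 95% interval 0.898% to 0.972%). The scRNA-seq libraries of benchmark 2 gave the same order, with 16.5% in T cells (1795 of 10863 reads), 0.00710% in monocultured KP cells (1 of 14079) and 0.266% in cocultured KP cells (26 of 9792, 0.174% to 0.389%). In benchmark 1 the allele was rare in all groups. It was 0.0134% of 52195 reads in T cells, 0.00285% in monocultured and 0.00440% in cocultured KP cells, and the intervals of the KP groups overlapped.

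A single allele marked the KP cells in ATAC. G12208A lies in ND5 (11742 to 13565), a subunit of respiratory complex I, within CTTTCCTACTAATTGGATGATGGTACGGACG (12193 to 12223), and changes codon 156 (G156E). Its share was 2.40% in monocultured KP cells, 2.79% in cocultured KP cells and 0.0195% in T cells. In scRNA-seq benchmark 2 it was 2.61%, 2.49% and 0.104%. In benchmark 1 it was 0.178% and 0.155% in the KP groups and 0 of 2036 reads in T cells, which allows up to 0.147%.

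**Figure D1:**
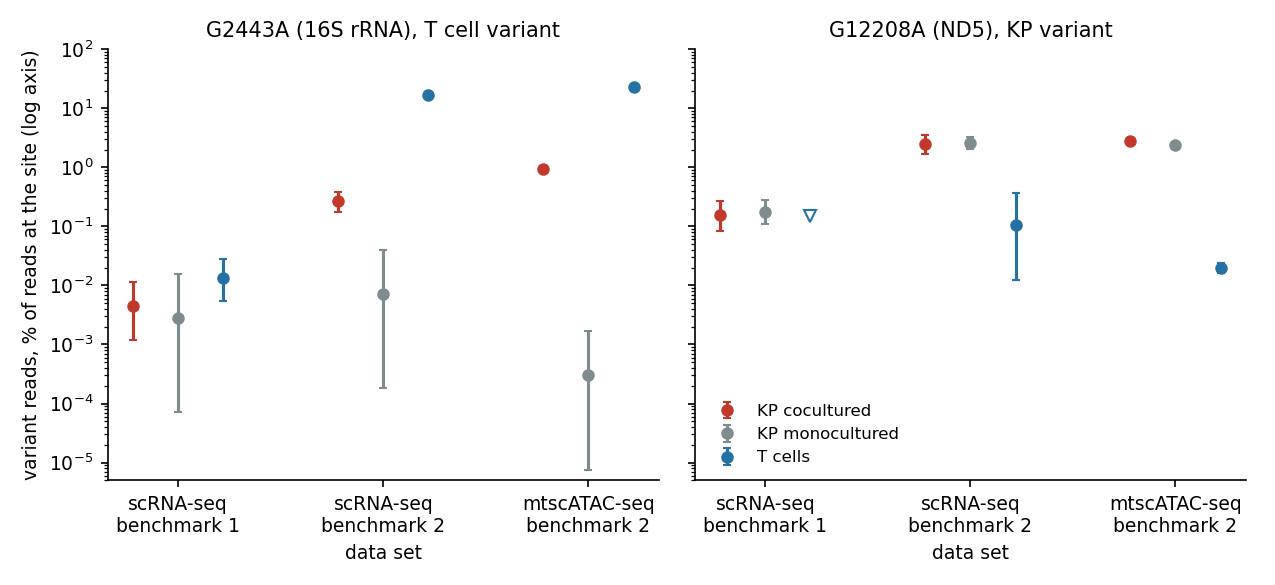
Share of reads with G2443A (left) and G12208A (right) in each data set, in % on a log axis, for KP cocultured (red), KP monocultured (grey) and T cells (blue), with exact 95% intervals and an open triangle at the limit of 3 reads where no variant read was seen. G2443A in cocultured KP cells lies between the other groups in both assays of benchmark 2.

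The T cell allele sat in a minority of cocultured KP cells. In ATAC, 242 of 3219 cocultured cells (7.52%, 6.63% to 8.48%) had a G2443A read, 223 of them with 2 or more, against 1 of 4928 monocultured KP cells and 7533 of 8050 T cells (93.6%). After thinning each cell to 18 reads the shares were 5.46% (153 of 2804 cells, 4.64% to 6.36%), 0 of 1741 held-out monocultured KP cells, which allows up to 0.172%, and 85.8% of T cells. Among 2693 cocultured cells with at least 20 reads at the site, 2483 had no variant read, 28 and 59 had shares under 1% and of 1% to 5%, 72 had 5% to 20%, 42 had 20% to 50% and 9 had 50% or more. The median share in the cells with a variant read was 6.90% (quartiles 1.65% and 19.2%), against 20.8% in T cells. In scRNA-seq benchmark 2, 11 of 1093 cocultured cells covered at the site had a variant read (1.01%, 0.503% to 1.79%), against 1 of 2329 monocultured KP cells and 531 of 1376 T cells.

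**Figure D2:**
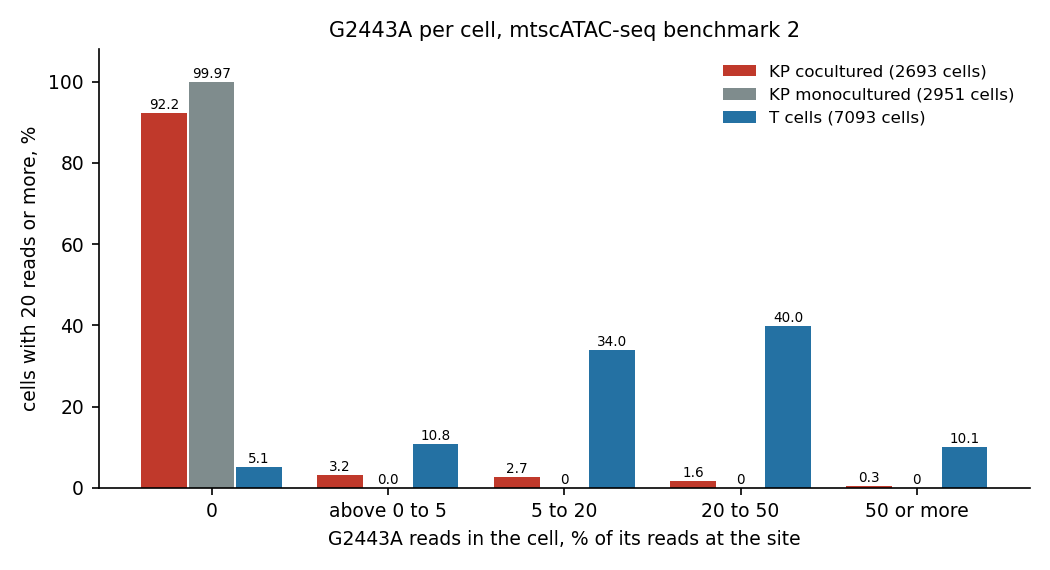
Cells by the share of G2443A among their reads at the site in mtscATAC-seq (horizontal axis, %), as % of cells with at least 20 reads, for KP cocultured (red, 2693 cells), KP monocultured (grey, 2951) and T cells (blue, 7093). No variant read was seen in 2483 of the cocultured cells, and 51 reached 20% or more.

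Many more alleles met the site rule in RNA than in DNA. T-enriched alleles numbered 125 in benchmark 1 and 21 in benchmark 2, and KP-enriched ones 43 and 9, against 1 of each in ATAC. Another such position lay within 10 bases for 102 of 124 T-enriched positions in benchmark 1 (82.3%) and 11 of 19 in benchmark 2 (57.9%), and for 26 of 41 (63.4%) and 4 of 9 (44.4%) KP-enriched ones. Few T-enriched alleles were seen in T cell DNA of benchmark 2. Of the 21 alleles of benchmark 2, 1 reached 1% there, which was G2443A, and 19 were under 0.1%. Of the 125 of benchmark 1, 0 reached 1% and 120 were under 0.1%, though T cell DNA of benchmark 1 itself is not analysed here. The counts depend on the site rule. With a T cell share of at least 5% they were 19 and 12, at 20 times the KP share 72 and 5, and in benchmark 2 with 1000 reads 6.

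In benchmark 1 the allele furthest apart was T13146C in ND5, at 56.8% in T cells, 11.6% in held-out monocultured KP cells and 26.7% in cocultured KP cells. Then came T6946A, T6948A, T6949A, G6951A and T6952A in TrnD, a transfer RNA gene, at 16.6% to 17.9% in T cells and 1.5% to 2.97% in monocultured KP cells. Their shares in cocultured KP cells were 21.1% to 22.8%, above those of the T cells by value, with overlapping intervals. G14904T and C14906T in CYTB, of respiratory complex III, had 8.09% and 8.00% in T cells and 2.89% and 2.87% in cocultured KP cells. C13333A in ND5 had 7.42% and 2.53%, and C1062T in TrnV had 6.01% and 0 of 1340 reads, which allows up to 0.224%.

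In benchmark 2 the leading alleles other than G2443A, which ranked 4th, lay at the end of TrnF (1 to 68), directly in front of mt-Rnr1, the gene of the small ribosomal RNA (70 to 1024). A68G had 20.6% in T cells, 3.09% in held-out monocultured KP cells and 5.34% in cocultured KP cells. C60T had 20.1%, 1.78% and 3.70%, and C61T had 18.9%, 2.33% and 3.8%. A65T, G55A, A66G, C67G and C61G followed at 15.8%, 12.4%, 9.65%, 8.37% and 8.58% in T cells, and G4986T in TrnW at 6.07%. C60T, C61T, A65T, A66G, C67G and A68G met the rule in both RNA tables, as did A13561G, where ND5 and ND6 overlap, and A11455C in ND4. C14133A in TrnE and T15676A, outside the annotated genes, were KP-enriched in both.

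Summed over the T-enriched alleles, cocultured KP cells stood above monocultured ones in each table. The shares of reads were 0.792% (0.784% to 0.801%) and 0.336% (0.330% to 0.343%) in RNA of benchmark 1, with 4.12% in T cells. In RNA of benchmark 2 they were 0.988% (0.889% to 1.09%) and 0.606% (0.520% to 0.702%), with 6.78% in T cells. The part of the monocultured cells used to choose these sites had 0.274% (0.217% to 0.340%). These parts of 1 library lay outside each other's intervals, but the sites were chosen for a low share in the choosing part. The gap therefore does not measure how far random parts differ. With another seed, which also changed the sites, the held-out part had 0.375% and cocultured cells 1.11%. The difference was 0.456 and 0.382 percentage points, and 0.935 in ATAC. Its size depended on the sites, since sites of the other benchmark gave a mean of 0.0418 in RNA and sites at 20 times the KP share 0.0923. After thinning, cells with an allele made up 70.9% of cocultured and 55.3% of monocultured KP cells and 90.2% of T cells in benchmark 1, at 553 reads per cell, with 1966 of 2904, 3094 of 3836 and 224 of 1669 cells deep enough. In benchmark 2, at 13 reads, they were 6.84% (5.31% to 8.66%), 3.56% (2.45% to 4.99%) and 39.5%. T-enriched sites of the other benchmark separated T cells from KP cells less. Those of benchmark 1 had 0.491% of reads in T cells and 0.2997% in held-out monocultured KP cells of benchmark 2. Those of benchmark 2 had 2.36% and 0.589% in benchmark 1. After thinning, 3.01% of T cells and 3.22% of held-out KP cells had an allele there. KP-enriched sites of benchmark 1 had 2.61% and 2.49% in benchmark 2, and those of benchmark 2 had 0.0269% and 0.574% in benchmark 1. The fitted mixing share of T cell alleles in cocultured KP cells was 24.8% (14.3% to 29.9%) in benchmark 1, 2.81% (1.01% to 9.85%) in benchmark 2, where another random seed gave 6.08%, and 3.83% in ATAC, from 2 sites. The RNA fits rest on alleles mostly not seen in T cell DNA of benchmark 2, so they may not measure a share of T cell DNA. The TrnD alleles of benchmark 1 also stood above the T cells by value, which a mixture would not give. In benchmark 2 the interval reached below 0 at some other settings. No test across libraries was made of these shares, and an exact two-sided permutation test of 2 against 2 RNA libraries, with 6 splits, cannot go below p = 0.333.

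Mitochondrial coverage per cell was higher in cocultured than in monocultured KP cells in each table. Median reads per position were 27.3 and 17.9 in benchmark 1, 14.9 and 12.5 in benchmark 2 and 45.6 and 12.3 in ATAC, with 20.9, 13.9 and 45.0 in T cells. The ratios of the medians were 1.52, 1.19 and 3.70. In ATAC the ratio of the means was 1.21, and monocultured cells had quartiles of 10.9 and 41.9 reads. In RNA the cocultured and monocultured KP cells also differed in reads per mitochondrial UMI, at 3.70 and 2.52 in benchmark 1 and 2.88 and 2.68 in benchmark 2. The median mitochondrial share of UMIs was 2.22% and 2.95% in benchmark 1 and 2.77% and 1.14% in benchmark 2, so in benchmark 1 the higher coverage came with a lower share of molecules.

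The comparison of T cells with KP cells, both cultured alone, checks the labels. T cell genes rose and keratin genes fell, and limma called 2522 genes higher and 2308 lower in T cells of the 10554 tested, with 2 libraries per group. All 26 genes of the T cell list rose. Ms4a4b, a T cell membrane protein, was higher by 8.32 on the log2 scale (SE 0.44, limma adjusted p = 7.96e-06), Ptprc, which encodes CD45, by 7.83 and Cd8b1, a CD8 chain, by 7.61. Of 8 epithelial and lung genes 7 fell and 1 rose, and the keratins Krt18, Krt8 and Krt19 fell, at -9.41, -9.12 and -8.01. All 18 MHC and antigen processing genes rose, with H2-K1, a class I heavy chain, at 6.28 and Psmb8, an immunoproteasome subunit, at 6.34. The interferon response list had 17 members up and 1 down of 19, with Stat1 at 4.80 and Gbp4 at 4.60.

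Effector genes were also higher in T cells, and metabolic and structural lists had more members down than up. In T cell activation and cytotoxicity 11 of 14 rose and 2 fell, with the chemokine Ccl5 at 7.0, the granule protein Nkg7 at 5.16 and the inhibitory receptor Ctla4 at 4.48. Glycolysis and hypoxia had 12 of 18 down and 1 up, with Vegfa, an angiogenic factor, at -3.45 and Pkm, a pyruvate kinase, at -3.30. Stress and immediate early genes had 10 of 15 down, with Ier3 at -5.24 and the chaperone Hspb1 at -4.92. The unfolded protein response had 8 of 16 down, with Asns, which makes asparagine, at -2.42. In the cytoskeleton list 16 of 29 fell and 2 rose, with Tubb6, a tubulin, at -4.94, and in the mesenchymal list 5 of 7 fell and 1 rose, with Sparc at -6.68 and Vim, vimentin, at -4.51. Nuclear oxidative phosphorylation genes had 10 of 29 down and 1 up, with Cycs, cytochrome c, at -2.05 and Cox5a at -1.70. S phase and G2 and mitosis genes each had 7 of 20 down, with Hells at -2.61 and Cdk1 at -3.35. Their medians were -1.48 and -0.35, and -3.28 and -0.31, in benchmarks 1 and 2, so most of the pooled difference came from benchmark 1, and 8 of 20 G2 and mitosis genes were higher in benchmark 2. None of the 13 mitochondrially encoded genes passed, with medians of -0.49 and 1.69.

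The other lists were mixed. Among p53 targets 7 of 13 rose and 1 fell, with Trp53inp1 at 3.96, and in the TNF and NF-kB response 7 of 17 rose and 5 fell. Mitochondrial dynamics had 3 of 25 up and 7 down, with Pink1, a kinase that marks damaged mitochondria, at 2.75. Of markers of other cells, both B cell genes tested rose, with Ighm at 5.84, as did 2 of 3 NK genes, with Klrd1 at 6.58, and 2 of 4 myeloid genes, with 1 down in each of the latter. Of 2 genes of the CD4 T cell list 1 rose and 1 fell. Adjusted over the list alone, the counts moved by at most 1 gene in any list and direction. By camera with a preset correlation 15 of the 21 lists passed, and with an estimated correlation none did, at adjusted p = 0.360 to 0.981 with an estimated correlation. Even the T cell list, with all 26 genes up, was at 0.360 there. A list that fails at that setting is therefore not shown to be unchanged. Mitochondrial dynamics had a median of 0.16 over both benchmarks, -0.06 from the mean log values and a camera direction of down.

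The count of genes moved with the settings. It was 2801 without monocultured KP library 1, 2957 without library 2 and 2336 without T cell library 1. It was 2466 with a pseudocount of 0.5, 2027 with no filter, 2106 with a stricter filter (922 up, 1184 down) and 1930 from the mean log values (760 up, 1170 down). The median over all genes was 0.09, and -0.03 after quantile normalization. Stat1 and Ctla4 did not pass with a pseudocount of 0.5 (limma adjusted p = 0.0550 and 0.127), with no filter (0.0890 and 0.155) or from the mean log values (0.176 and 0.255). Gbp4, Nkg7 and Tubb6 did not pass with no filter or from the mean log values. Psmb8, Ccl5 and AW112010 were lost from the mean log values, and Pkm with no filter. Without T cell library 1, Cycs, Cox5a, Cdk1, Hells and Asns no longer passed, at limma adjusted p = 0.130, 0.147, 0.113, 0.0710 and 0.107, nor did Asns without T cell library 2, at 0.0684.

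The next question was how KP cells differed after coculture. The genes furthest up in both benchmarks included Cxcl1, a chemokine that attracts neutrophils, at 1.63 on the log2 scale (SE 0.30, 1.77 in benchmark 1 and 1.49 in benchmark 2), and Cdh1, E-cadherin, at 1.63 (1.29 and 1.96). AW112010, a transcript induced in immune cells on activation, was at 1.88 (1.80 and 1.97), and was also higher in T cells than in KP cells, by 5.20. Ugt2b34, a glucuronosyltransferase, was at 2.32, Gkn2 at 2.24, Sytl2 at 1.64, Abhd2 at 1.41, Slco2a1, a prostaglandin transporter, at 1.39, Aff1 at 1.29 and Cpt1a, which takes fatty acids into mitochondria, at 1.28. The lowest in both were Tuba1a, an alpha tubulin, at -1.72, Ctxn1 at -1.03, Dctpp1, a nucleotide phosphatase, at -0.92, Siva1 at -0.89, Lsm2 at -0.85, the histone gene H2afz at -0.78, Nme4 at -0.76, the ribosomal protein genes Rplp0 and Rpsa at -0.72 and -0.70, and Tmsb10, thymosin beta 10, at -0.69.

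None of these passed. Limma called 0 of 10554 genes, with 559 at an unadjusted p under 0.05 and a smallest adjusted p of 0.809. edgeR also called 0, with 332 at an unadjusted p under 0.05. DESeq2 called 37, all up, of which 34 also rose in T cells against the same monocultured KP libraries, where independent lists would share 8.84. Named after their values were seen, the other 3 were Dmbt1, Gm26870 and Muc5b. Part of this overlap may come from the shared libraries. In 20 simulations of unchanged groups against them, DESeq2 called 3.5 genes up on average and 7 at most. Of the first 37 genes 92.7% were higher in T cells, against 94.6% of the 37 here. At most 0 genes were called in both comparisons there, against 34 here. The T cells were simulated as unchanged as well, with at most 0 genes called higher, so the simulations cannot size the overlap. AW112010 and Ms4a4b were among the 37, at DESeq2 adjusted p = 0.00333 and 0.00614. Over 5771 genes at 0.2 per 10000 or more, differences in both benchmarks had the same sign for 61.3%, with r = 0.129 across genes, which are not independent replicates, against 0.862 for T cells and KP cells. Of these genes 39 were higher by 1 or more in both, 0 lower by as much in both and 47 apart in opposite directions. The median over all genes was 0.19, and -0.0059 after quantile normalization, 0.26 with a pseudocount of 0.01 and 0.06 with 0.5, and all differences here stand against that shift.

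Leaving out a library gave a few calls. Without monocultured KP library 2 there were 41 (12 up, 29 down), with mitotic genes such as Ccnb2 at -3.52 and Cdc20 at -2.47, and Fosb at 2.69, Atf3 at 2.5, Gkn2 at 2.99 and Ugt2b34 at 2.59. Without cocultured KP library 2 there were 15 (12 up, 3 down), with Ugt2b34 at 3.00 and Tuba1a at -2.78. Without monocultured KP library 1 there were 3, Apob, Gm26917 and mt-Atp8, and without cocultured KP library 1 there were 2, Gm26917 and Neat1, all up and named after their values were seen. Leaving out either T cell library gave 0. The lone KP library is then assumed to vary like the other groups.

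**Figure D3:**
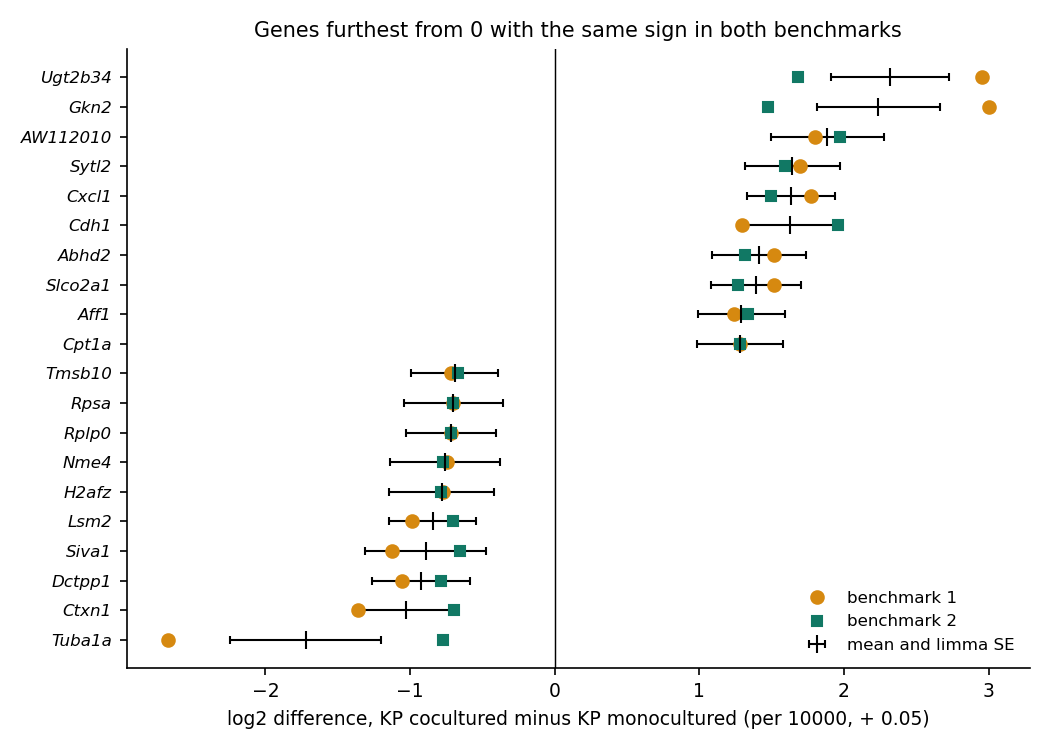
Log2 difference between cocultured and monocultured KP cells (horizontal axis, per 10000 plus 0.05) for the 10 highest and 10 lowest genes by the rule, with benchmark 1 (orange circles), benchmark 2 (green squares) and the mean with its limma standard error (black). The mean was highest for Ugt2b34, at 2.32, and lowest for Tuba1a, at -1.72, and no gene passed the test.

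Immune response lists had medians above 0 in cocultured KP cells, with no member passing over all genes. Over both benchmarks the medians were 0.28 for TNF and NF-kB, 0.26 for MHC, 0.18 for interferon and 0.29 for T cell genes, against 0.19 for all genes. In the same order they were 0.13, 0.10, 0.05 and 0.11 after quantile normalization (all genes -0.0059), 0.16, 0.04, 0.06 and 0.04 with a pseudocount of 0.5 (0.06), and 0.38, 1.28, 0.76 and 3.63 with edgeR (0.02), so the interferon, MHC and T cell lists did not stand above all genes under each scaling. In the TNF and NF-kB response the median difference was 0.40 in benchmark 1 and 0.52 in benchmark 2, and 12 of 17 members were higher in both, led by Cxcl1, the adhesion molecule Vcam1 at 1.27 and the feedback inhibitors Tnfaip3 at 1.23 and Nfkbia at 0.91. In MHC and antigen processing the medians were 0.03 and 0.49, and 14 of 18 were higher in both, with the peptide loading gene Tapbp at 1.39, the peptide trimming enzyme Erap1 at 1.30, H2-K1 at 1.12 and H2-T23 at 1.07. In monocultured KP cells 10 of the 18 were under 0.05 per 10000 in benchmark 1 and 9 in benchmark 2. Some therefore count as higher on a difference near 0, such as Psmb8 and H2-Q4, each at 0.02 in benchmark 1. By camera both lists passed with a preset correlation, at adjusted p = 0.00734 and 0.0452, but not with an estimated one, at adjusted p = 0.936 with an estimated correlation for each. With no benchmark block the MHC list did not pass (camera adjusted p = 0.221). Adjusted over the list alone, 2 members of the TNF list rose, Cxcl1 and Vcam1. The interferon response list had medians of 0.07 and 0.48 and did not pass (camera adjusted p = 0.461), with Stat1 at 0.64 and 2.28 and Irf1 at 0.11 and 2.62. T cell genes had medians of 0.00 and 0.59 and did not pass (0.352), with Ms4a4b at 0.07 and 1.65 and Ccr7 at 0.01 and 1.17. In benchmark 2, 10 of 1151 cocultured KP cells (0.869%, 0.417% to 1.59%) had at least 3 of 7 T cell markers, against 0 of 2543 monocultured ones, which allows up to 0.118%. Benchmark 1 had 1 of 2904 cocultured and 1 of 7572 monocultured KP cells with as many, with overlapping intervals. In cells without any marker, the medians of benchmark 2 were 0.51 for TNF, 0.37 for MHC, 0.46 for interferon and 0.03 for T cell genes. The 7 markers are members of the T cell list, so its lower median follows in part from this choice of cells.

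The medians of the mitochondrially encoded, nuclear oxidative phosphorylation and G2 and mitosis lists had opposite signs in the benchmarks, though some members kept theirs. Mitochondrially encoded genes had a median of -0.36 in benchmark 1 and 2.5 in benchmark 2, with mt-Nd3, a complex I subunit, at -0.30 and 2.93. Nuclear oxidative phosphorylation genes had 0.17 and -0.45, with Ndufs1 at 0.57 and 0.36 and Uqcrh at -0.26 and -0.45. G2 and mitosis genes had -2.33 and 0.46, with Ccnb2 at -3.25 and -0.38 and Cdc20 at -2.60 and 0.12, and S phase genes had -0.67 and -0.05, with Gins2 at -1.09 and -0.42. Camera with a preset correlation put the mitochondrially encoded list up (adjusted p = 7.33e-04) and oxidative phosphorylation (2.59e-04), S phase (2.24e-07), G2 and mitosis (1.38e-14) and the cytoskeleton list (0.0442) down. All 5 were lost with an estimated correlation (camera adjusted p = 0.936), a setting that no list passed between T cells and KP cells either. The cytoskeleton list was also lost with no benchmark block (camera adjusted p = 0.0741). It holds genes related to tunneling nanotubes and had medians of 0.08 and -0.26, with Myo10, a myosin of filopodia, at 0.89 and Tuba1b at -0.87. In benchmark 2, 21.7% of cocultured KP cells and 0 of 2543 monocultured ones had 10% or more mitochondrial UMIs, and in benchmark 1 these were 7.61% and 16.2%.

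Other lists did not pass. Stress and immediate early genes had 0.79 and -0.41 (camera adjusted p = 0.911), with Fosb at 2.58 and 1.10, Atf3 at 2.55 and 0.12 and Hspb1 at -1.57 and -0.43. Mitochondrial dynamics, import and stress had 0.35 and -0.01 (0.911), with the stress transcription factor Ddit3 at 1.15, Opa1, of inner membrane fusion, at 0.66 and Rhot1, which moves mitochondria along microtubules, at 0.62. Glycolysis and hypoxia had 0.40 and -0.12 (0.911), with Vegfa at 1.09, P4ha1 at 0.84 and Hk1, a hexokinase, at 0.81. P53 targets had 0.43 and 0.12 (0.359), with Trp53inp1 at 0.94 and Mdm2 at 0.60, and the unfolded protein response had 0.13 and 0.38 (0.368), with Atf6 at 1.12 and Trib3 at 1.08. Epithelial and lung genes had -0.07 and -0.02 (0.578), with Krt7 at -0.64 and Krt19 at 0.36, and adjusted over the list alone 1 member, Cdh1, rose. Mesenchymal genes had 0.19 and 0.00 (0.862), with Zeb1 at 0.68. T cell activation had 0.00 and 0.13 (0.741). The B cell, myeloid, NK and CD4 T cell lists, of 2, 4, 3 and 2 tested genes, had camera adjusted p = 0.883, 0.911, 0.911 and 0.637. With an estimated correlation all lists here lay at adjusted p = 0.936 or 0.956. The stress, mesenchymal, T cell activation, B cell and NK lists had medians over both benchmarks of 0.19, 0.20, 0.14, 0.08 and 0.04 but a camera direction of down, against the shift of all genes. After quantile normalization the medians of the mesenchymal, mitochondrial dynamics and glycolysis lists turned from 0.20, 0.18 and 0.12 to -0.06, -0.02 and -0.02, that of the NK list from 0.04 to -0.0020, that of glycolysis also turned with edgeR and DESeq2, to -0.07 and -0.05, and with a pseudocount of 0.01 that of the epithelial list turned from -0.03 to 0.01, and to 0.0016 with 0.5.

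**Figure D4:**
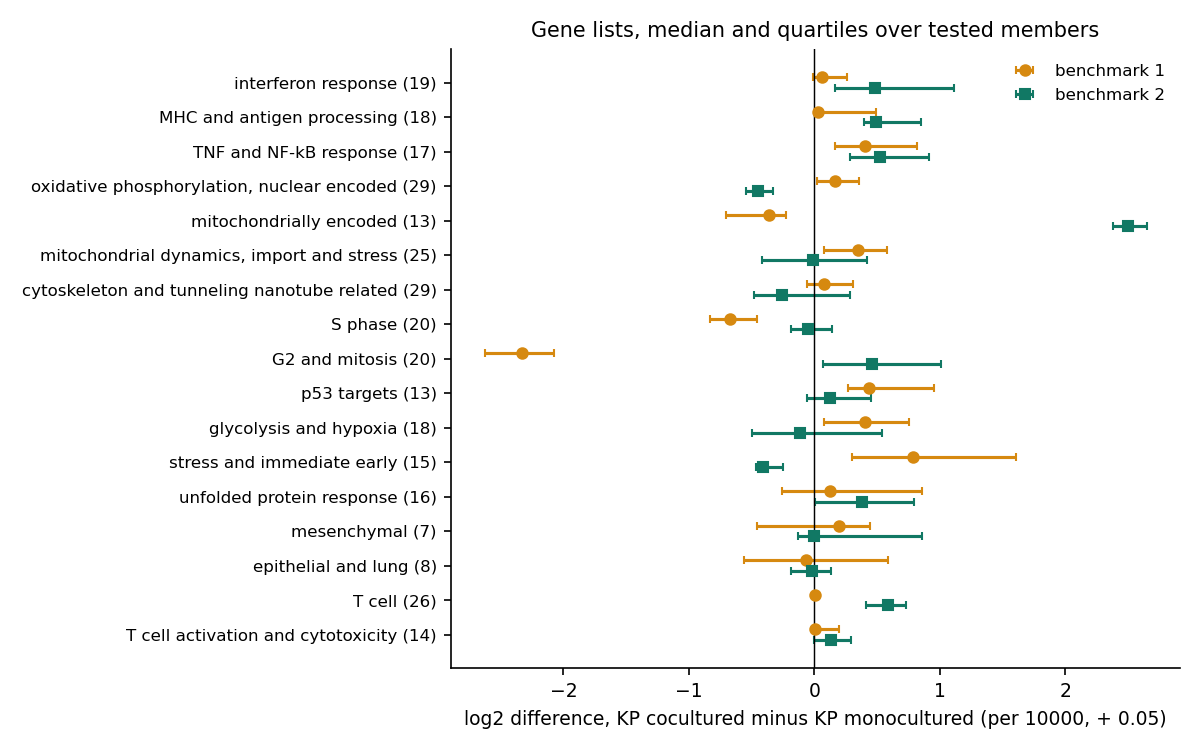
Median log2 difference between cocultured and monocultured KP cells over the tested members of each gene list (number in brackets), with quartiles, in benchmark 1 (orange circles) and benchmark 2 (green squares). G2 and mitosis genes stood at -2.33 and 0.46 and mitochondrially encoded genes at -0.36 and 2.5.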

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

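The tests of even spread, whole T cells, RNA doublets, T cell DNA, the oligo at other ends and the monocultured KP libraries were chosen only after the results were seen.

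G2443A in cocultured KP cells of benchmark 2 has several technical candidate sources. T cell DNA spread evenly over all cells is excluded as the source of all these reads. A share of 5% or more was seen in 123 cells, against at most 52 in 200 simulations at the pooled share. A lower even background beside another source was not simulated and stays open. Whole T cells with T cell DNA alone are excluded as the source of all these cells. The KP allele G12208A was read in 17.6% (8.40% to 30.9%) of cells at 20% or more of the T cell allele and in 39.1% (28.8% to 50.1%) of those under 5%. It was read in 0.760% of monocultured T cells at 20% or more of the T cell allele and in 0.683% of all T cells. Median mitochondrial reads per cell were 12884 and 19683 in the cocultured sets and 9392 in the T cells at 20% or more. Those T cells were cultured without KP cells, so the test does not exclude whole T cells read together with KP DNA from the coculture. In RNA whole T cells are excluded as the source of all carriers. Of the 11 carriers 18.2% (2.28% to 51.8%) had 3 or more T cell markers and 9 had none, against 99.6% of T cells with 3 or more. Only 7 of 1082 other cocultured cells had 3 or more markers, however, so a part stays open. The reference holds no doublets, so doublets with little T cell RNA stay open. Median UMIs were 33536 in carriers and 24680 in the 1082 other cells. Reads given to the wrong library by a shared barcode are excluded as the main source, since 3.72% (1.71% to 6.94%) of ATAC carriers shared a barcode with a T cell and 0 of 11 in RNA, but other ATAC cells shared 1.07%, so a small part stays open. Cells at 5% or more had fewer G12208A reads than those without the T cell allele, at 0.662% and 0.469% against 2.85%, while the 87 cells under 5% had 3.02%, so some whole T cells stay open for the former, and for both ATAC doublets of a T cell and a KP cell, free T cell DNA taken up by some cells and transfer of T cell mitochondria, as the design names, stay open, the last 2 as untested hypotheses.

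The second pattern is the set of T-enriched RNA alleles of benchmark 2 in front of mt-Rnr1. Variants of the T cells' mitochondrial DNA are excluded as the source of most, since 1 of 21 alleles reached 1% in T cell DNA. Bases of the template switch oligo of the 5' kit (TTTCTTATATGGG) placed at the annotated start are excluded, since 30% of the alleles equalled it, though in benchmark 1 62.5% did, which leaves it open there. With the last base of the oligo at positions 61 and 68, however, 10 of 11 alleles equalled it, as many as in 3 of 1000 shuffled oligos. RNA that starts directly after these positions may thus be the source of these alleles, as a hypothesis found on the same data. In benchmark 1 the best 2 positions of the last base, 67 and 68, gave 9 of 10, as many as in 20 of 1000 shuffled oligos.

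The third pattern is that gene lists went opposite ways between benchmarks 1 and 2, which was not tested. The benchmark 2 minus benchmark 1 differences of the medians were 2.86 for mitochondrially encoded genes, 2.79 for G2 and mitosis and -1.20 for stress and immediate early genes. Cells with 10% or more mitochondrial UMIs are excluded as the whole source, since without them the gaps were 2.74 for G2 and mitosis and 1.51 for the mitochondrially encoded genes, whose lower gap follows in part from choosing cells by those genes. For G2 and mitosis a difference between the monocultured KP libraries is excluded as the source, since the benchmark 2 minus benchmark 1 median was -0.0167 there (quartiles -0.57 and 0.23), against 2.80 in cocultured KP cells and 3.00 in T cells, and a different response in each coculture, or a difference between benchmarks that spared the monocultured KP cells, stays open. For mitochondrially encoded genes it was -2.80 in monocultured KP cells (-3.07 and -2.61) and 0.21 in cocultured ones, so a difference between the monocultured libraries may be the source, and for stress genes 0.64 (0.40 and 1.88) does not decide.

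Cells with T cell RNA made up 0.869% of cocultured KP cells in benchmark 2, above the monocultured cells at 0 of 2543, and all 10 also had Krt8 or Krt18.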

How the results depend on the processing

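Alternatives were set for each result, some chosen after the data were seen and called added here, and no named gene past the threshold and no mean over both RNA benchmarks reversed. In benchmark 1 alone, ATAC sites gave -0.00119 points of T-enriched share and -0.0384 points of cells, and the medians of the glycolysis, mesenchymal, mitochondrial dynamics, epithelial and NK lists changed sign under other scalings, as given above. For cocultured KP cells, 0 genes held with no replicate block, as under all settings that kept every library except DESeq2, added, with 37 (range without a library 0 to 41). With no replicate block T cells differed from KP cells in 4566 genes, against 4830 with the benchmark block. The count was 2466 with a pseudocount of 0.5, 2027 with no filter, 2106 with a stricter filter and 1930 from mean log values (2336 to 5338 without a library). Of gene lists 7 passed, 5 with no replicate block and 0 with an estimated correlation, both added. Of 1090 values of 55 genes named for cocultured cells 1080 stayed on their side of the threshold and 10 became stronger, 8 of them without a library, and of 598 values of 30 genes named for T cells 564 stayed and 34 became weaker. The difference in T-enriched share in RNA, 0.419 percentage points, was 1.28 at a T cell share of at least 5%, 0.0923 at 20 times the KP share, 0.495 on all monocultured cells, 0.599 with another seed, 0.525 without T cell marker cells, 0.0418 with the other benchmark's sites and 0.125 with ATAC sites, added (0.382 to 0.456 for a single benchmark). In ATAC it was 0.935, and 0.0671 with RNA sites. The difference in cells with an allele was 9.44 points in RNA (3.28 to 15.6), 3.56 at 20 times the KP share, 3.46 with the other benchmark's sites and 0.251 with ATAC sites, in benchmark 2 alone 0.324 at a T cell share of 5%, and in ATAC 5.46, 3.39 with 2 reads and 7.52 not thinned. The mixing share was 24.8% in benchmark 1 and 2.81% in benchmark 2, and over the alternatives 17.6% to 28.5% and 1.21% to 6.08%, and 4.01% in ATAC at a T cell share of 5%. Its interval in benchmark 2 was -7.18% to 15.2% with 1000 reads and -1.24% to 8.94% at 20 times the KP share. It was -0.157% to 14.4% without T cell marker cells and widest with the sites of benchmark 1, at -47.2% to 32.8%. T-enriched sites in benchmark 1 were 19 at a share of 5% and 72 at 20 times. In benchmark 2 they were 6 with 1000 reads, 38 at 0.5%, 12 at 5%, 50 at 2 times and 5 at 20 times, and in ATAC 3 at 0.5% and 2 at 2 times. Ratios of mean coverage were 1.67, 1.31 and 1.21. These follow from fewer or more sites or genes where the rule changed, and otherwise the cause was not tested. Depth limits the shares of cells, taken at 13 reads per cell in RNA of benchmark 2 and 18 in ATAC, and G2443A in cocultured cells rests on 26 variant reads of 9792 in RNA of benchmark 2 and 2479 of 265269 in ATAC.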

Other observations

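The tests of T cell RNA in MHC genes were chosen after the result was seen. Gzmb, the granzyme B gene of activated killer cells, was read in 56.1% of T cells of benchmark 2 and in 0 of 1669 of benchmark 1, which allows up to 0.180%. Their median depths were 17325 and 5229 UMIs, and with each cell thinned to 2000 UMIs the shares were 16.8% and 0. In benchmark 2 it was also read in 0.608% of cocultured and 0.0786% of monocultured KP cells.

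A hypothesis is that T cell RNA in the library did not give the higher values of MHC genes in cocultured KP cells of benchmark 2. For 8 of the 9 members at 0.05 per 10000 or more in monocultured KP cells, those at least 4-fold higher in T cells, the median share of T cell RNA that would give the difference was 6.02% (quartiles 3.34% and 15.4%), above the 1.77% of the highest of 26 T cell genes. The estimate takes T cells cultured alone as the source, and T cells in coculture were not measured, so T cell RNA richer in MHC transcripts stays open. For the other 9 members, lower in KP cells, the share was 0.911% (0.560% and 1.48%), inside the 0.201% to 1.77% of the T cell genes, so T cell RNA may give their difference. The same estimate for T cell genes was 0.557% in benchmark 2 and 0.000919% in benchmark 1, where the highest was 0.141% and 5 of 8 MHC members at 0.05 or more had a median of 5.18% (1.28% and 11%).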
